A study of Rattus norvegicus with 16 samples.

How the data were processed

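Lung total RNA with a biotin label was measured on 16 microarrays. The labels place the arrays in 4 groups of 4 biological replicates: spontaneously hypertensive (SH) rats in air, SH rats in sulfur dioxide (SO2), Sprague Dawley (SD) rats in air and SD rats in SO2. Replicates are numbered here within each group, in the order of the numbers in the sample titles. Dose, duration of exposure, time of sampling and age of the animals are not given in the sources used here.

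The deposited table holds 1 intensity per probe set and array, on a linear scale. The submitters' processing notes name the Affymetrix software GCOS, and its version and algorithm are not given in the sources used here. The mean intensity of each array without its highest and lowest 2% of probe sets lay between 500.099 and 500.111, so the deposited scaling was kept; the rule was to keep it if these means lay within 10% of each other. Detection calls were not used here. The number of arrays limits the precision.

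The table has 15923 probe sets, of which 57 control probe sets were left out. Of the other 15866, 12783 had 1 gene symbol in the platform annotation, 312 had several and 2771 had none here; probe sets with several symbols or none were tested but not named. Symbols were checked through Entrez identifiers against a RefSeq gene table of assembly GRCr8, used for names only. Of the probe sets with 1 symbol, 12748 matched and 0 symbols changed.

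Values were taken as log2(intensity + 16). This offset understates the change of dim probe sets. The 30% of probe sets with the lowest mean over all 16 arrays were left out, which left 11106 probe sets and 8060 genes with 1 symbol. Tests used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on mean level), with 1 mean for each of the 4 groups, 12 residual degrees of freedom and no covariate. P-values were adjusted by Benjamini-Hochberg over the 11106 probe sets, and a probe set was called at an adjusted p under 0.05. The 5 comparisons were SO2 against air in each strain, the difference between these effects (the interaction), and SH against SD rats in air and in SO2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

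Gene lists were tested with camera from limma at a preset inter-gene correlation of 0.01, with 1 probe set per gene (the one with the highest mean) and Benjamini-Hochberg adjustment over the lists of a comparison. Of 30 lists, 28 had at least 5 members tested; B cell and plasma cell genes had 4 and thymus and developing T cell genes had 3, so neither was tested. Among the 28 lists were markers of neutrophils, macrophages, mucous and goblet cells, club cells, ciliated cells, alveolar type I and type II cells, basal and squamous epithelium, T and natural killer cells, mast cells with eosinophils and type 2 immunity, endothelium, smooth muscle, cardiac and skeletal muscle, erythroid cells with platelets, and adipocytes. The other lists held genes of inflammatory cytokines and chemokines, antioxidant (Nrf2) defence, sulfur metabolism, the acute phase and IL-6 response, extracellular matrix and remodelling, proliferation, the interferon response, blood pressure and vasoactive signals, the stress response, the immediate early response, the circadian clock, the glucocorticoid response, and sterol and fatty acid synthesis. Camera with an estimated correlation and fry, with and without regard to direction, were run as alternatives. Camera compares a list with the other genes, whereas fry asks whether the members themselves change.

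The genes named were fixed by rule. For each comparison they are the 12 largest rises and 12 largest falls among called probe sets whose groups do not overlap on any array, up to 4 members of smallest p from each list with a called member or a called shift, and Suox, Cd36 and Ephx2 whatever their values. Where a comparison had under 10 called genes, the 10 with the smallest unadjusted p are named as not passing. A gene with several probe sets is represented by the one with the highest mean. Of the list members so chosen, the text gives those called, those of the smallest p and, for the clock list in SD rats, all 4. Any other gene named is said to have been chosen after its values were seen.

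The groups, comparisons, lists, naming rule, filter, offset and a first set of other analysis choices were fixed before the data were examined. This first set held offsets of 1 and 64, quantile normalization, arrays centred on their medians, no filter on dim probe sets, the lower 50% left out, probe sets of a gene averaged, the replicate number as a block, eBayes without a trend or with a robust prior, array weights, only the arrays of the groups compared, the number in the sample titles as a covariate, and each array left out in turn. Title numbers ran from 40 to 43 in SH air and were 44 and 51 to 53 in SH SO2. They were 45, 46, 54 and 55 in SD air and 47 to 50 in SD SO2. They separated SH air fully from SH SO2 and from SD air, so this covariate can absorb those contrasts. Alternatives chosen after seeing the data were the 10th percentile of intensity and the actin 3' to 5' ratio of each array as covariates, singly, together, and together without the array labelled SD air replicate 2, and leaving out the 2 arrays with the highest actin ratios. Contrasts averaged over strains or over exposures were also added after seeing the data.

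The tests were tried on simulated data for the 11106 probe sets of each comparison. In each, 67 probe sets were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold. Of the probe sets changed 2-fold, limma recovered 85.1% for SO2 in SH rats, 80.6% for SO2 in SD rats, 49.3% for the interaction, 82.1% for the strains in air and 77.6% for the strains in SO2. At 4-fold the shares were 95.5%, 98.5%, 90.9%, 97% and 100%, and at 1.5-fold 31.3%, 40.3%, 13.4%, 41.8% and 40.3%. The Benjamini-Hochberg threshold becomes stricter when fewer probe sets change. These shares therefore do not give the chance of finding a change limited to a few probe sets, which would be lower. With 1 list of the 8060 genes shifted by 0.4 on the log2 scale, camera called that list and 0 of the 27 others. The simulated genes varied independently, whereas the T cell and natural killer cell list had an estimated correlation of 0.335 in the data. This trial therefore cannot show how often camera falsely calls lists whose genes vary together.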

Results

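Gene expression in the lung was measured in spontaneously hypertensive (SH) rats, an inbred strain with high blood pressure, and in Sprague Dawley (SD) rats, an outbred stock, after exposure to air or to the irritant gas sulfur dioxide (SO2). Each of the 4 groups had 4 arrays, labelled as biological replicates. The series title names the SH rat as a model of airway disease caused by SO2, so the comparisons ask what SO2 changed in each strain, whether the strains responded differently, and how the strains differed in air and in SO2. Values are signals (linear intensity) as mean ± SD with n = 4, and changes are on the log2 scale with their standard error (SE). All p-values are from limma unless camera is named.

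The arrays were close to one another in overall level, with median signals from 250.2 to 281.8. Correlations of log2 values ran from 0.921 to 0.972 within groups and from 0.913 to 0.974 between groups, and 0 of 120 pairs of arrays were identical. Signs of background and RNA quality varied. The 10th percentile of signal averaged 19.6 ± 1.58 in SH air, 22.6 ± 4.12 in SH SO2, 20.3 ± 2.97 in SD air and 21.5 ± 3.49 in SD SO2 arrays. The 3' to 5' signal ratio of actin, which rises as RNA is degraded, averaged 1.78 ± 0.402, 2.14 ± 0.77, 1.53 ± 0.159 and 1.92 ± 0.687 in the same groups. The array labelled SD air replicate 2 had SH-like signals of strain-dependent genes: Terf2ip, which encodes a telomere-binding protein, measured 693.8 on it, against 1982 to 2363 on the other SD air arrays and 424.8 to 733.2 on the SH air arrays. Counts and list calls that involve SD rats in air are therefore also given without this array, with values of selected genes, an exclusion among the planned leave-one-out settings whose emphasis was chosen after the values were seen.

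In SH rats, SO2 exposure left no gene past the threshold. Il1b, which encodes the inflammatory cytokine interleukin-1 beta, had signals of 902.1 ± 232 in SO2 and 510.5 ± 121 in air (0.80, SE 0.184). Car3, a carbonic anhydrase abundant in fat and muscle, had the smallest p, with 587.3 ± 107 against 336.1 ± 40.7 (0.77, SE 0.15). Lower values in SO2 were measured for Tap2, a peptide transporter for antigen presentation (-1.31, SE 0.306), for Stap2, a signalling adaptor (-1.61, SE 0.347, with a signal of 54.42 ± 24.5 in SO2), and for Dnaja1, a co-chaperone of heat shock protein 70 (-0.75, SE 0.181). On SH SO2 replicate 2 the Stap2 signal of 19 lay under the array's 10th percentile of 26.8, so the size of the Stap2 change is uncertain. Also among the 10 genes of smallest p were the noncoding RNA Meg3 (0.76), Nsmaf (0.67), the splicing factor Srsf5 (0.62), the transcription factor Glis2 (0.48) and the fatty acid binding protein Fabp5 (-0.53). All 10 had an adjusted p of 0.402, the smallest of this comparison. Cd36, a fatty acid transporter, measured 262.2 ± 48.1 in SO2 and 526.7 ± 264 in air (-0.87, adjusted p = 0.949), and -0.58 without SH air replicate 1. Values for Suox, the sulfite oxidase that turns sulfite into sulfate, and Ephx2, soluble epoxide hydrolase, were -0.18 (adjusted p = 0.96) and -0.026 (adjusted p = 0.992).

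Limma called 0 of 11106 probe sets for SO2 in SH rats, with 537 at an unadjusted p under 0.05 where 555 were expected by chance. Air and SO2 arrays did not overlap in 4.17% of probe sets, against 2.86% by chance. Leaving out SH SO2 replicate 4 gave 1 called probe set, that of Tap2 (-1.67, adjusted p = 0.0418, in a range of 0.0418 to 1 over the alternatives).

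Among gene lists in SH rats, 3 fell by camera. The stress response list (heat shock and unfolded protein genes) fell by 0.145 on average over 34 genes (adjusted p = 0.00308; adjusted p = 0.656 with an estimated correlation). It was led by Dnaja1 and by Hspa1a, an inducible heat shock protein 70, at 1093 ± 385 in SO2 and 3191 ± 2280 in air (-1.35, adjusted p = 0.653). Alveolar type II cell genes, which include the surfactant machinery, fell by 0.159 over 17 genes (adjusted p = 0.00892; adjusted p = 0.555 with an estimated correlation), with Pla2g1b at -0.52 and Scd, a fatty acid desaturase, at -0.56, or -0.34 without SH air replicate 4. Macrophage markers fell by 0.118 over 16 genes (adjusted p = 0.0212; adjusted p = 0.555 with an estimated correlation), with Fabp5 at -0.53 and Gpnmb at -0.56. No member of these lists was called over all probe sets, and 3, 0 and 1 fell when adjusted over the list alone.

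The stress and macrophage shifts moved with array quality, and the alveolar type II shift less so. With the 10th percentile of signal and the actin ratio as covariates, chosen after seeing the data, the means were -0.0373 for stress response genes (adjusted p = 0.458, range 2.26e-05 to 0.567 over 33 settings), -0.123 for alveolar type II cell genes (0.089, range 0.00141 to 0.089) and -0.0418 for macrophage markers (0.34, range 0.00225 to 0.34), and 0 lists were called. The stress call was also lost without SH air replicate 3 (mean -0.0826, adjusted p = 0.0639), the alveolar type II call without SH SO2 replicate 1 (0.0817), and the macrophage call without SH air replicate 2 (0.0947) or SH SO2 replicate 1 (mean -0.0617, adjusted p = 0.201). With the title number as a covariate the macrophage (0.116) and stress calls (0.182) were lost. Title numbers separated the SH air from the SH SO2 arrays fully, so an effect of order cannot be told apart from that of exposure here.

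SD rats likewise had no gene past the threshold with SO2. The smallest p belonged to Htra1, a secreted serine protease, with 1057 ± 86.3 in SO2 and 1792 ± 276 in air (-0.74, SE 0.131, adjusted p = 0.192). In order of p it was followed by Gtf2i, a transcription factor, at -0.51, and by Irgm2, an interferon-inducible GTPase, with 1231 ± 93.4 against 817.4 ± 80.6 (0.58, SE 0.12). Next were Bmp1, a protease that processes procollagen, at 0.75 (SE 0.162), and Cdh11, a mesenchymal cadherin, at -0.68 (SE 0.147). The others were LOC100912041 at 0.65, the calcium pump Atp2a3 at 0.45, the tetraspanin Cd81 at -0.39, Cd99 at -0.65, and Srsf5 at 0.64, close to its 0.62 in SH rats. Adjusted p-values of these 10 genes lay between 0.192 and 0.329. Cd36 (0.15, adjusted p = 0.944), Ephx2 (-0.30, adjusted p = 0.717) and Suox (-0.16, adjusted p = 0.857) did not pass. Without the array labelled SD air replicate 2 the 10 genes had adjusted p-values of 0.234 to 0.28, and Cd36 changed sign, to -0.19 (adjusted p = 0.921, range 0.764 to 0.987).

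Limma called 0 of 11106 probe sets for SO2 in SD rats, with 915 at an unadjusted p under 0.05 against 555 by chance, and 0 also without the array labelled SD air replicate 2. Arrays of the 2 exposures did not overlap in 3.54% of probe sets (2.86% by chance). Leaving out SD air replicate 4 gave 3 calls, among them Htra1 (-0.86, adjusted p = 0.0183) and Cdh11 (-0.81, adjusted p = 0.043); leaving out SD air replicate 3 gave 1, and leaving out SD SO2 replicate 1 gave 1, Bmp1 (0.95, adjusted p = 0.00852). Over the alternatives the adjusted p ranged from 0.0183 to 0.806 for Htra1, from 0.043 to 0.806 for Cdh11 and from 0.00852 to 0.806 for Bmp1.

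Circadian clock genes rose most of the lists in SD rats, by a mean of 0.398 over 15 genes (camera adjusted p = 0.000102; adjusted p = 0.115 with an estimated correlation). Per2, a core repressor of the clock, measured 728.8 ± 125 in SO2 and 402.9 ± 193 in air (0.94, SE 0.26). Cry2, its partner, was at 0.70 (SE 0.185), Wee1, a clock-controlled kinase, at 0.90 (SE 0.253), and Nr1d2, a clock nuclear receptor, at 0.61 (SE 0.172). None passed over all probe sets, with adjusted p-values of 0.329 to 0.366, while 5 clock genes were higher when adjusted over the list alone. This was the 1 list that fry called in a direction (adjusted p = 0.0416). Per2 was at 1.18 without the array labelled SD air replicate 2 (adjusted p = 0.234, range 0.144 to 0.806). Chosen after their values were seen, Dbp was at 1.05 (0.58 without SD air replicate 1) and Per1 at 1.12 (0.42 without SD air replicate 3), while Bmal1 (-0.67), Nfil3 (-0.44, or -0.21 without SD air replicate 1) and Clock (-0.35, or -0.19 without SD SO2 replicate 1) were the list's 3 members below 0. For the whole list without that array the mean was 0.462 (adjusted p = 1.81e-05, range 7.6e-06 to 0.00279 over 33 settings).

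**Figure D1:**
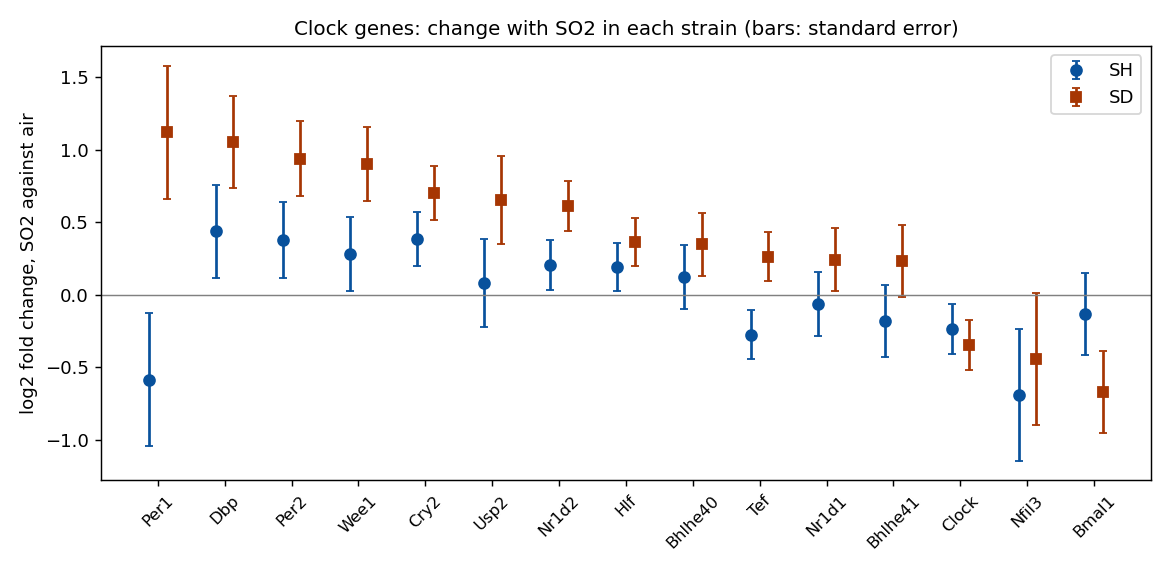
Change with SO2 against air (log2 fold change, vertical axis) of the 15 clock genes tested, in SH rats (circles) and SD rats (squares), with bars of 1 standard error from limma and 4 arrays per group. In SD rats 12 genes lie above 0, and Clock, Nfil3 and Bmal1 lie below 0.

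Immune and epithelial lists also rose in SD rats. T cell and natural killer cell genes rose by 0.325 over 19 genes, 18 of them above 0 (adjusted p = 0.000102; adjusted p = 0.386 with an estimated correlation), with Gzmb, a cytotoxic granule protease, at 0.94 (0.42 without SD air replicate 3, where it measured 34 against 161.6 to 271.7 on the other SD air arrays) and Lat, a T cell receptor adaptor, at 0.34. Interferon response genes rose by 0.175 over 28 genes (adjusted p = 0.00284; adjusted p = 0.386 with an estimated correlation); Gbp2, an interferon-induced GTPase, was at 0.57, and Tapbp, a peptide-loading chaperone, went the other way at -0.43. A second probe set of the list member Mx2, chosen after its values were seen and not the one tested in the list, was lower too, with mean signals of 44.2 in SO2 and 283.8 in air (-1.91, SE 0.402, adjusted p = 0.242, a bound because the SO2 signals lay near background), and at -1.38 without the array labelled SD air replicate 2 (SE 0.304, adjusted p = 0.258). Ciliated cell genes rose by 0.228 over 9 genes (adjusted p = 0.0167; adjusted p = 0.412 with an estimated correlation), with the axonemal Tekt1 at 0.56 and the tubulin Tubb4b at 0.24. Mast cell, eosinophil and type 2 genes rose by 0.197 over 15 genes (adjusted p = 0.04; adjusted p = 0.386 with an estimated correlation), with the eosinophil chemokine Ccl11 at 0.44 (0.28 without SD SO2 replicate 4) and Hdc, the histamine-forming enzyme, at 0.40 (0.25 without the array labelled SD air replicate 2). Sterol and fatty acid synthesis genes rose by 0.125 over 27 genes (adjusted p = 0.04; adjusted p = 0.386 with an estimated correlation), with Idi1 at 0.49 and Tmem97 at 0.37.

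Cardiac and skeletal muscle genes, which in lung tissue can come from heart muscle around the pulmonary veins, fell by 0.32 in SD rats over 21 genes, 18 of them below 0 (adjusted p = 0.000102; adjusted p = 0.386 with an estimated correlation). Myl7, an atrial myosin light chain, measured 570.6 ± 151 in SO2 and 950.8 ± 300 in air (-0.71), and Tcap, a sarcomere protein, was at -0.64. On SD air replicate 3, Myl7 measured 1386 against 742.3 to 913.1 on the other SD air arrays, and Tcap 694.2 against 289.4 to 397.4. Without SD air replicate 3 the list mean was -0.178 (adjusted p = 0.0294, range 5.6e-07 to 0.0294), with Myl7 at -0.51 and Tcap at -0.37. Extracellular matrix and remodelling genes fell by 0.139 over 33 genes (adjusted p = 0.00842; adjusted p = 0.386 with an estimated correlation), with Loxl1, an elastin cross-linking enzyme, at -0.59 (-0.37 without SD air replicate 3) and the protease inhibitor Timp2 at -0.38. Of these 7 lists no member was called over all probe sets; adjusted over the list alone, 1 interferon gene was higher and 1 lower, 1 ciliated cell gene was higher, and 0 changed in the others.

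The muscle, T cell and clock calls in SD rats held in all 33 settings with the preset correlation. Without the array labelled SD air replicate 2, 6 of the 8 lists were called; mast cell (adjusted p = 0.139, range 0.0188 to 0.197) and sterol genes (0.147, range 0.00678 to 0.295) were not. The count fell to 5 without SD air replicate 1 and to 5 without SD SO2 replicate 1. Without SD air replicate 1, interferon (0.0842, range 1.96e-05 to 0.0842), mast cell (0.0512) and sterol genes (0.06) were lost. Without SD SO2 replicate 1 the lost lists were ciliated cell (0.124, range 0.00104 to 0.181), matrix (0.0685, range 0.0014 to 0.0685) and mast cell genes (0.0744). Calls were also lost for ciliated (0.151) and mast cell genes (0.151) without SD SO2 replicate 2, interferon (0.0524) and sterol genes (0.295) without SD SO2 replicate 3, and mast cell genes without SD air replicate 3 (0.0555) or SD SO2 replicate 4 (0.0508). Without SD SO2 replicate 4 the interferon mean was 0.0905 (0.0281). With the actin ratio as a covariate, the ciliated cell call was lost (0.111).

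**Figure D2:**
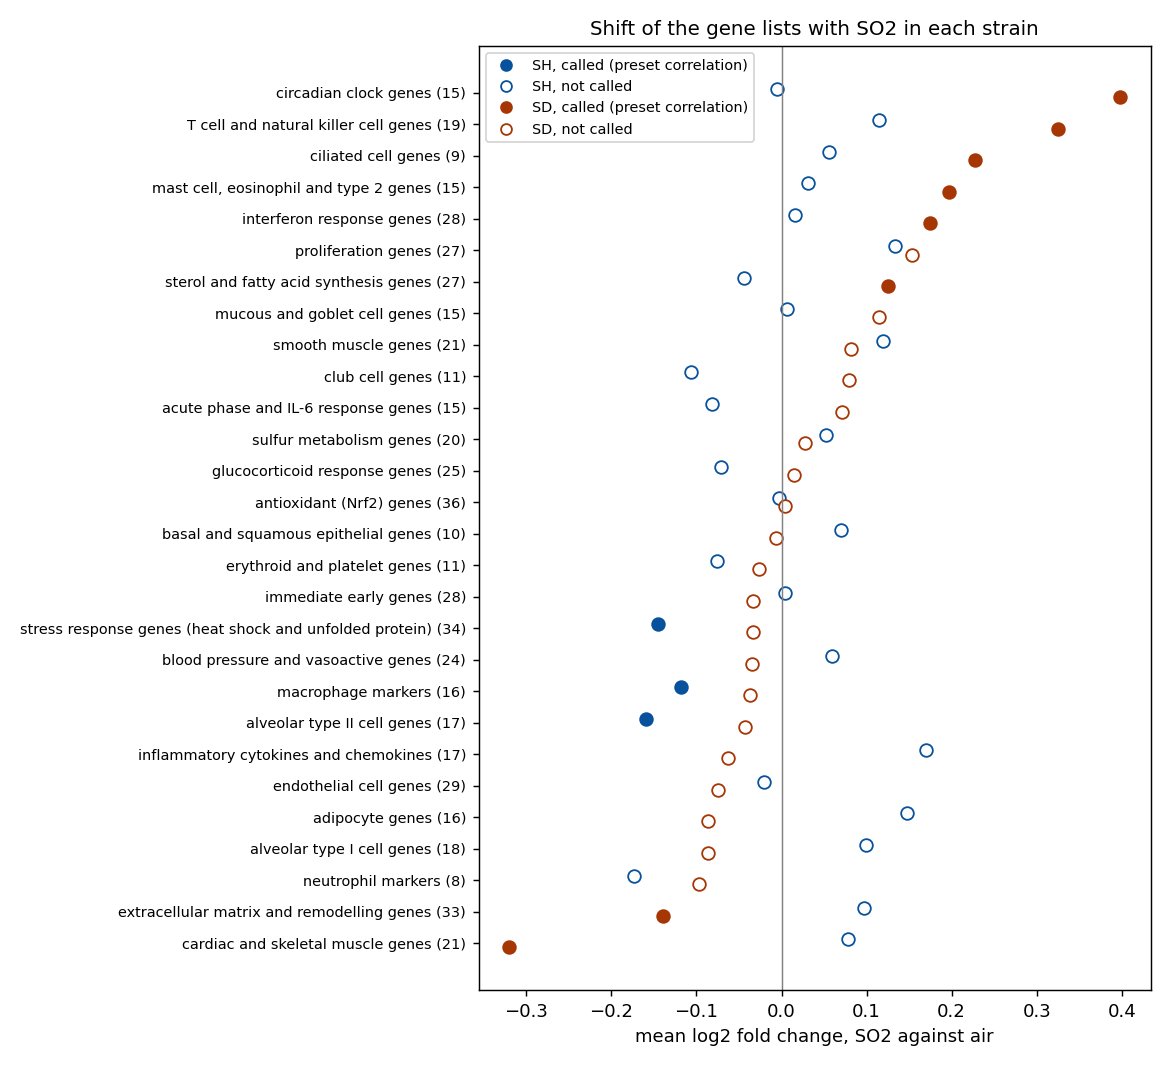
Mean log2 fold change with SO2 against air (horizontal axis) of the 28 gene lists in SH rats (blue) and SD rats (red), with the number of genes tested in brackets. Filled points were called by camera at the preset correlation, 3 in SH rats and 8 in SD rats, and none of them at an estimated correlation.

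The inflammatory, antioxidant, sulfur metabolism, mucous and club cell lists were among those that camera called in neither strain. Inflammatory cytokines and chemokines averaged 0.17 in SH rats (adjusted p = 0.102) and -0.0635 in SD rats (0.639). The fry test without regard to direction called the inflammatory list in SH rats (adjusted p = 0.0134). Antioxidant (Nrf2) genes averaged -0.00302 (0.798) and 0.00389 (0.65). Sulfur metabolism genes, which include Suox, averaged 0.0523 (0.624) and 0.0273 (0.65). Neutrophil markers were at -0.173 (0.244) and -0.0976 (0.639), mucous and goblet cell genes at 0.00653 (0.823) and 0.115 (0.857), and club cell genes at -0.107 (0.239) and 0.0789 (0.639). Adjusted over the list alone, 2 inflammatory genes were higher in SH rats and 2 lower in SD rats, 1 club cell gene was lower in SH rats, and 0 changed in the antioxidant, sulfur, neutrophil and mucous lists. The signs of median, mean and test differed for mucous genes (median -0.0162 with a downward test in SH rats) and club cell genes (median 0.0165 in SH rats), and the test of antioxidant genes in SD rats was downward at a mean above 0. Proliferation genes averaged 0.133 in SH rats (0.225) and 0.153 in SD rats (0.162), smooth muscle genes 0.119 (0.102) and 0.0813 (0.263). Endothelial cell genes averaged -0.0207 (0.798) and -0.0749 (0.0555), and alveolar type I cell genes 0.0998 (0.443) and -0.0864 (0.263). Values for basal and squamous epithelial genes were 0.0695 (0.624) and -0.00671 (0.639), for acute phase and IL-6 response genes -0.0819 (0.324) and 0.0709 (0.614), for erythroid and platelet genes -0.0755 (0.324) and -0.0262 (0.588), and for blood pressure and vasoactive genes 0.0598 (0.624) and -0.035 (0.466). Immediate early genes were at 0.0039 (0.902; median -0.00823) and -0.0337 (0.857), and glucocorticoid response genes at -0.0712 (0.624) and 0.0147 (0.879; median -0.035 and a downward test). Adjusted over the list alone, 1 acute phase gene and 2 erythroid genes were lower in SH rats, 1 blood pressure gene was lower in SD rats, and 0 changed in the others of these 10 lists. Over all lists not called, adjusted p ran from 0.102 to 0.902 in SH rats and from 0.0555 to 0.879 in SD rats.

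The test of the difference between the strains' responses also called no gene. The smallest p belonged to Car3 (1.07, SE 0.212) and Pxdc1 (0.71, SE 0.142), both with an adjusted p of 0.447; Car3 was at 0.77 with SO2 in SH rats and measured 277.9 ± 19.6 against 349.1 ± 50.3 in SD rats. Next in order of p was Gtf2i at 0.58, and Il1b, further down, was at 1.04 (SE 0.26). On the negative side were Stat3, a transcription factor of cytokine signalling, at -1.01 (SE 0.252), Stap2 at -1.83, the antimicrobial peptide gene Defb4 at -0.90, Adam3a at -0.98, Secisbp2l at -0.79 and the proteasome subunit Psmc5 at -0.65, all with an adjusted p of 0.959. The size for Stap2 is uncertain, as its signal on 1 SH SO2 array lay near background. The second Mx2 probe set, chosen after its values were seen, was at 2.30 (SE 0.569, adjusted p = 0.959, with the same limit from background), and at 1.77 without the array labelled SD air replicate 2 (adjusted p = 0.735). Cd36 (-1.02), Ephx2 (0.28) and Suox (-0.0228) had adjusted p-values of 0.981, 0.994 and 0.998. Cd36 was at -0.68 without the array labelled SD air replicate 2 (adjusted p = 0.883, range 0.724 to 1). Limma called 0 of 11106 probe sets, with 516 at an unadjusted p under 0.05 against 555 by chance, and 0 without the array labelled SD air replicate 2.

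For the lists, camera called 6 differences between the strains' responses. Muscle genes were higher in SH than in SD responses by 0.398 over 21 genes (adjusted p = 0.000569; adjusted p = 0.362 with an estimated correlation), with Tcap at 1.04 and Myl7 at 0.75. Extracellular matrix genes were higher by 0.236 over 33 genes (adjusted p = 0.00145; adjusted p = 0.234 with an estimated correlation), with Ccn1, a matrix-associated signalling protein, at 1.55 and Loxl1 at 0.94. Adipocyte genes were higher by 0.233 over 16 genes (adjusted p = 0.0457; adjusted p = 0.231 with an estimated correlation), with Pck1 at 0.98 and the glycerol channel Aqp7 at 0.55. Clock genes were lower by a mean of -0.403 over 15 genes (adjusted p = 0.00145; adjusted p = 0.231 with an estimated correlation), with Per1 at -1.71 (-1.01 without SD air replicate 3) and Tef at -0.54. Sterol genes were lower at -0.169 over 27 genes (adjusted p = 0.0149; adjusted p = 0.234 with an estimated correlation), with Idi1 at -0.72 and Tmem97 at -0.59. T cell and natural killer cell genes were lower at -0.21 over 19 genes (adjusted p = 0.0457; adjusted p = 0.544 with an estimated correlation), with the cytotoxic genes Prf1 at -0.80 and Nkg7 at -0.59. Adjusted over the list alone, 0 members of these 6 lists changed. The other lists called in 1 strain had no called difference: stress response genes at -0.111 (adjusted p = 0.118), alveolar type II cell genes at -0.116 (0.12) and macrophage markers at -0.081 (0.128), all of which fell in SH rats. The same held for lists that rose in SD rats, with interferon genes at -0.158 (0.0821), ciliated cell genes at -0.173 (0.118) and mast cell, eosinophil and type 2 genes at -0.166 (0.128). Clock genes in SH rats had a mean of -0.00532 and a median of 0.0796 with an upward test (adjusted p = 0.859). Means in SH rats were 0.115 for T cell (0.347), 0.0784 for muscle (0.595), 0.0968 for matrix (0.239) and -0.044 for sterol genes (0.324). Adipocyte genes were called in neither strain, at 0.147 in SH rats (0.225) and -0.0864 in SD rats (0.32). Over all lists not called, adjusted p of the difference ran from 0.0716 to 0.899.

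Of these 6 calls the clock difference held in all 33 settings with the preset correlation, and not with an estimated correlation or with fry in a direction. With the title number as a covariate the muscle (0.0725, adjusted p = 0.718, range 6.17e-06 to 0.718) and matrix differences (0.0627, adjusted p = 0.624, range 7.58e-05 to 0.624) were not called. Title numbers are confounded with exposure in SH rats, so these losses cannot be read as an effect of order. Without SD air replicate 3 the muscle difference was 0.256 (adjusted p = 0.0237). Without the array labelled SD air replicate 2, 3 lists were called, and T cell (adjusted p = 0.118, range 1.75e-05 to 0.225), adipocyte (0.078, range 0.0137 to 0.406) and sterol genes (0.056, range 0.000691 to 0.0981) were not. The same count of 3 was reached without SD SO2 replicate 3, where T cell (0.0814), adipocyte (0.061) and sterol genes (0.0814) were lost; sterol genes were also lost without SH SO2 replicate 2 (0.0698). T cell genes were lost too without SH air replicate 1 (0.0752), 2 (0.057) or 4 (0.0957), SH SO2 replicate 1 (0.225) or 4 (0.0879), SD air replicate 1 (0.103) or 3 (0.119), and SD SO2 replicate 1 (0.156) or 4 (0.159). Their mean was -0.133 without SD air replicate 3 and -0.135 without SD SO2 replicate 4, against -0.342 without SD air replicate 4 (0.00055) and -0.363 without SD SO2 replicate 2 (0.000702). Adipocyte genes were lost without SH air replicate 1 (0.0616), 2 (0.0841) or 4 (0.0522), SH SO2 replicate 1 (0.0877) or 2 (0.0807), SD air replicate 1 (0.0666) or 3 (0.0605), and SD SO2 replicate 1 (0.0523) or 2 (0.131). Over the 33 settings the adipocyte call was kept in 13 and lost in 20, and the T cell call was kept in 20 and lost in 13.

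Between the strains in air, no gene passed with all 16 arrays. Cd300c2, a leukocyte receptor, measured 409.9 ± 13.5 in SH and 814.7 ± 208 in SD rats (-0.93, SE 0.158), and RT1-T24-4, of the major histocompatibility complex (MHC) class I family, 1252 ± 132 and 3430 ± 1190 (-1.37, SE 0.245). With Cep295, a centrosomal protein (1.18, SE 0.207), they had the smallest adjusted p, 0.0504. Loxl1 was at -1.03 (adjusted p = 0.0816), Cyp2f4, a cytochrome P450 of club cells, at -0.84 (0.0979), Terf2ip at -1.42 (0.114), and Cxcl14, a chemokine of epithelia, at 1.41 (0.141). Ifngr1, a chain of the interferon gamma receptor (-0.52), Plekhb1 (-0.83) and Fam32a (-0.79) had an adjusted p of 0.141 as well. Cd36, a gene known to be defective in some SH lines, measured 526.7 ± 264 in SH and 1493 ± 775 in SD rats (-1.43, adjusted p = 0.179), while Ephx2 (0.0204, adjusted p = 0.995) and Suox (0.32, adjusted p = 0.812) did not pass.

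Limma called 0 of 11106 probe sets between the strains in air, with 709 at an unadjusted p under 0.05 against 555 by chance and 7 at an adjusted p under 0.10; arrays did not overlap in 4.02% (2.86% by chance). Without the array labelled SD air replicate 2, 86 were called, 43 higher and 43 lower in SH rats, from 68 named genes, with 1079 at an unadjusted p under 0.05. Without SH air replicate 1 the count was 1. In the fit without the array labelled SD air replicate 2, Terf2ip was at -1.83 (SE 0.195, adjusted p = 0.000147), Cd300c2 at -1.11 (SE 0.135, 0.000414), RT1-T24-4 at -1.65 (SE 0.21, 0.000528), Cxcl14 at 1.80 (SE 0.235, 0.000548) and Eln, elastin, at -1.45 (SE 0.199, 0.00088). Cd36 was then at -1.77 (SE 0.32, adjusted p = 0.0107) and Loxl1 at -1.07 (SE 0.218, adjusted p = 0.0239). Over the alternatives the adjusted p of these genes reached 1 at the highest, and at the lowest 0.000143 for Terf2ip, 0.000155 for Cd300c2, 0.000528 for RT1-T24-4, 0.000143 for Cxcl14, 0.00088 for Eln, 0.0107 for Cd36 and 0.0239 for Loxl1.

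Of the lists in air, 4 were higher in SH rats and 1 lower. Interferon response genes were higher by 0.298 over 28 genes, 23 of them above 0 (camera adjusted p = 5.18e-08; adjusted p = 0.199 with an estimated correlation). Ifit3, an antiviral effector, measured 508.4 ± 94.1 in SH and 276.1 ± 84.9 in SD rats (0.87, adjusted p = 0.19), and Usp18, a brake on interferon signalling, was at 0.74 (0.275). Clock genes were higher by 0.272 over 15 genes (adjusted p = 0.00584; adjusted p = 0.199 with an estimated correlation), with Per2 at 1.05 and Bhlhe40 at 0.63. Neutrophil markers were higher by 0.382 over 8 genes (adjusted p = 0.0143; adjusted p = 0.491 with an estimated correlation), with the chemokine receptor Cxcr1 at 0.90 and the calcium-binding S100a8 at 0.96. Stress response genes were higher by 0.118 over 34 genes (adjusted p = 0.0269; adjusted p = 0.808 with an estimated correlation), with Dnaja1 at 0.56 and Herpud1 at 0.59. Matrix genes were lower at -0.14 over 33 genes (adjusted p = 0.0143; adjusted p = 0.491 with an estimated correlation), with Eln at -1.13 and Loxl1 at -1.03. No member was called over all probe sets, and adjusted over the list alone 7 interferon, 1 clock and 1 neutrophil gene were higher, 3 matrix genes were lower, and 0 stress genes changed. Some members went the other way, of which Cxcr2 and Trib3 were chosen after their values were seen. The neutrophil gene Cxcr2 measured 47.5 to 116.9 in SH and 85.2 to 242.3 in SD air arrays. Signals of the stress gene Trib3 were 133.1 to 215.6 and 179.1 to 353.2. For the lists not called, adjusted p ran from 0.0571 to 0.875. The fry test without regard to direction called 3 lists, the interferon (adjusted p = 0.00282), club cell (0.00692) and matrix lists (0.00692).

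The interferon call in air held in all 33 settings with the preset correlation, and not with an estimated correlation or with fry in a direction. Without the array labelled SD air replicate 2 there were 5 list calls, and the stress call was lost (adjusted p = 0.0722, range 6.54e-05 to 0.651). The stress call was lost as well without SH air replicate 3 (mean 0.0559, adjusted p = 0.595), SD air replicate 3 (0.0619) or SD air replicate 4 (mean 0.0667, adjusted p = 0.522), and its mean was 0.191 without SD air replicate 1 (6.54e-05). Lost too were the clock call without SD air replicate 1 (0.0746, range 0.000283 to 0.0746), and the neutrophil call without SH air replicate 2 (0.0543, range 0.000147 to 0.194) or SD air replicate 3 (mean 0.233, adjusted p = 0.0983). Matrix genes were lost without SH air replicate 2 (0.0676, range 0.000665 to 0.922), SH air replicate 4 (0.0651) or SD air replicate 3 (0.0551). With the title number as a covariate the neutrophil (0.194), matrix (0.922) and stress calls (0.586) were lost. Title numbers separated the SH air from the SD air arrays fully, so order and strain cannot be told apart here. The list count was 3 without SH air replicate 2 and 2 without SD air replicate 3.

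Under SO2 the strains differed, and among called genes with 1 symbol, each by 1 probe set, the largest differences were those of the MHC class I genes RT1-CE16 and RT1-A, then Terf2ip and Cd36; a second probe set of Mx2, with SD signals near background, is given apart. The class I gene RT1-CE16 measured 2199 ± 502 in SH and 291.5 ± 271 in SD rats (3.31, SE 0.698, adjusted p = 0.0244), and RT1-A 131.4 ± 23.9 and 1378 ± 730 (-3.01, SE 0.593, adjusted p = 0.0146). RT1-A3 (1.36) and RT1-CE5 (1.41, adjusted p = 0.0489) were higher and RT1-T24-4 lower (-1.87) in SH rats. Cd36 measured 262.2 ± 48.1 in SH and 1574 ± 612 in SD rats, a 5.45-fold difference (-2.45, SE 0.345, adjusted p = 0.000731), and Terf2ip 386.1 ± 77.1 and 2441 ± 527 (-2.61, SE 0.286, adjusted p = 7.22e-05). Defb4, an antimicrobial beta-defensin, measured 6277 ± 495 in SH and 17730 ± 2340 in SD rats (-1.49, SE 0.157, adjusted p = 5.77e-05).

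Further genes higher in SH rats in SO2 were Ccn1 (2.17, SE 0.311, adjusted p = 0.000828), Cxcl14 (2.04, SE 0.304, adjusted p = 0.00119), the mitochondrial creatine kinase Ckmt1 (1.82), the methyltransferase Inmt (1.56), Fam107a (1.42), Mlc1 (1.34), the elastase Cela1 (1.31), the glutathione transferase Gsta3 (1.26) and the calcium-binding Tesc (1.23). Lower in SH rats were the keratin gene Krt79 (-1.76), Gp2 (-1.69), Stap2 (-1.58), Cd300c2 (-1.36), the club cell cytochrome P450 gene Cyp2a3 (-1.32), the alpha globin gene Hba-a3 (-1.28) and the phosphatase gene Ptprj (-1.27). Some SH SO2 signals of Stap2 (lowest 19) and Krt79 (lowest 38.7) lay near background, so the sizes of these differences are uncertain. Ephx2 (0.30, adjusted p = 0.665) and Suox (0.29, adjusted p = 0.597) did not pass.

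Grouped by list, 2 of 17 inflammatory genes were called higher, Cxcl14 and Il1b (1.16, SE 0.184, adjusted p = 0.00235), and the same number when adjusted over the list alone. Of 28 interferon genes, 3 were called higher, Tapbp (0.58), Irf7, a master regulator of interferon genes (1.01), and the antiviral Mx2 (0.80); adjusted over the list alone, 8 were higher and 2 lower. A second Mx2 probe set, chosen after its values were seen, had the smallest p of the comparison, with mean signals of 1017 in SH and 44.2 in SD rats (adjusted p = 3.36e-05). Its SD signals of 29.2 to 60 lay near the 10th percentile of those arrays, 17.8 to 25.5, so the difference of 4.11 (SE 0.402) is a bound and not a size. Among 11 club cell genes 1 was called higher and 2 lower, Gsta3 against Cyp2f4 (-1.26) and Cyp2a3, and 2 higher and 4 lower adjusted over the list alone. Of the acute phase and IL-6 response genes Stat3 was called lower (-1.13, SE 0.178, adjusted p = 0.00235), and Lbp was at -0.58 (adjusted p = 0.117); 2 were lower adjusted over the list alone. Single calls were Ccn1 in the matrix list (Lum at 0.69, adjusted p = 0.08; 2 higher over the list alone) and Thbd, thrombomodulin, of endothelial cells (0.46; Gja5 at 0.38, adjusted p = 0.275; 1 higher). Others were Hba-a3 of erythroid and platelet genes (Hbb at -0.42, adjusted p = 0.244; 1 lower), Cd36 of blood pressure and vasoactive genes (Vegfb at -0.47, adjusted p = 0.342; 1 lower) and Fam107a of glucocorticoid response genes (Sgk1 at 0.44, adjusted p = 0.305; 1 higher). None of these lists was called by camera, with adjusted p-values of 0.0506 for the inflammatory and interferon lists and 0.992 as the highest of all lists. Other probe sets of Stat3 (-0.47, limma adjusted p = 0.235) and of Thbd (0.14 and 0.096, adjusted p = 0.931 and 0.892) were smaller and not called. The fry test without regard to direction called 12 lists, among them the inflammatory (adjusted p = 3.46e-08), interferon (1.77e-05) and club cell lists (2.64e-05). Fry asks only whether members change, and these lists hold called genes, so its calls are no sign of a shift against other genes.

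As whole lists, muscle genes were higher in SH rats in SO2 by 0.402 over 21 genes, 17 of them above 0 (camera adjusted p = 1.34e-05; adjusted p = 0.295 with an estimated correlation). Tcap was called (1.08, adjusted p = 0.0407), Myl7 was at 0.70 (adjusted p = 0.167), and 3 were higher adjusted over the list alone. T cell and natural killer cell genes were lower at -0.269 over 19 genes (adjusted p = 0.00476; adjusted p = 0.469 with an estimated correlation), with Prf1 at -0.84 and Nkg7 at -0.72 and 2 lower adjusted over the list alone. Sterol and fatty acid synthesis genes were lower at -0.163 over 27 genes (adjusted p = 0.042; adjusted p = 0.295 with an estimated correlation), with Sqle, a step of cholesterol synthesis, at -1.34 (-0.84 without SH SO2 replicate 2), the fatty acid synthase Fasn at -0.44 and 4 lower adjusted over the list alone. The T cell call was lost without SH SO2 replicate 1 (adjusted p = 0.0547, range 8.91e-06 to 0.0547), and its mean was -0.422 without SD SO2 replicate 2. Lost was also the sterol call without SH SO2 replicate 1 (0.0547, range 0.00814 to 0.118), SH SO2 replicate 2 (0.118), SD air replicate 3 (0.0558) or SD SO2 replicate 3 (0.0684). The list count was 5 without SH SO2 replicate 2, SH SO2 replicate 3 or SD SO2 replicate 3, 6 without SH SO2 replicate 4, 8 without SH air replicate 3, SH air replicate 4, SD air replicate 1 or the array labelled SD air replicate 2, and 9 without SD SO2 replicate 4.

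Limma called 90 of 11106 probe sets between the strains in SO2, 45 higher and 45 lower in SH rats, from 72 named genes and 16 probe sets with no single gene symbol. At an unadjusted p under 0.05 there were 1127 (555 by chance), arrays did not overlap in 5.58% of probe sets (2.86% by chance), and 86 of the 90 called did not overlap. The count was 50 without SH SO2 replicate 3, 57 without SH SO2 replicate 2, 58 without SD SO2 replicate 4 and 115 without the array labelled SD air replicate 2, which enters through the shared spread. Of 32 named genes called, 16 were called in every alternative run, among them Cd36, Terf2ip, Defb4, Ccn1, Cxcl14, Il1b, Stat3, Cyp2f4 and RT1-T24-4. The other 16 were lost in at least 1 leave-one-out setting, 14 of them without SH SO2 replicate 3, 12 without SH SO2 replicate 2 and 10 without SD SO2 replicate 4; RT1-CE5 was lost in 22 settings (highest adjusted p 0.163), Mx2 in 17 (0.17), Tcap in 16 (0.134), RT1-CE16 in 8 (0.134) and RT1-A in 4 (0.0973).

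The calls in air and in SO2 overlapped. Without the array labelled SD air replicate 2, 33 of the 86 probe sets called in air were among the 90 called in SO2. All 33 had the same direction, and 0.697 would be expected if the calls were independent. They are not, since both comparisons estimate the spread of a probe set from arrays of all the groups. That array was also singled out for its SH-like strain-dependent genes, and leaving it out can raise the overlap. The size of the overlap beyond chance therefore cannot be read from these numbers. With all 16 arrays, 85 of the 90 had the same sign in air.

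**Figure D3:**
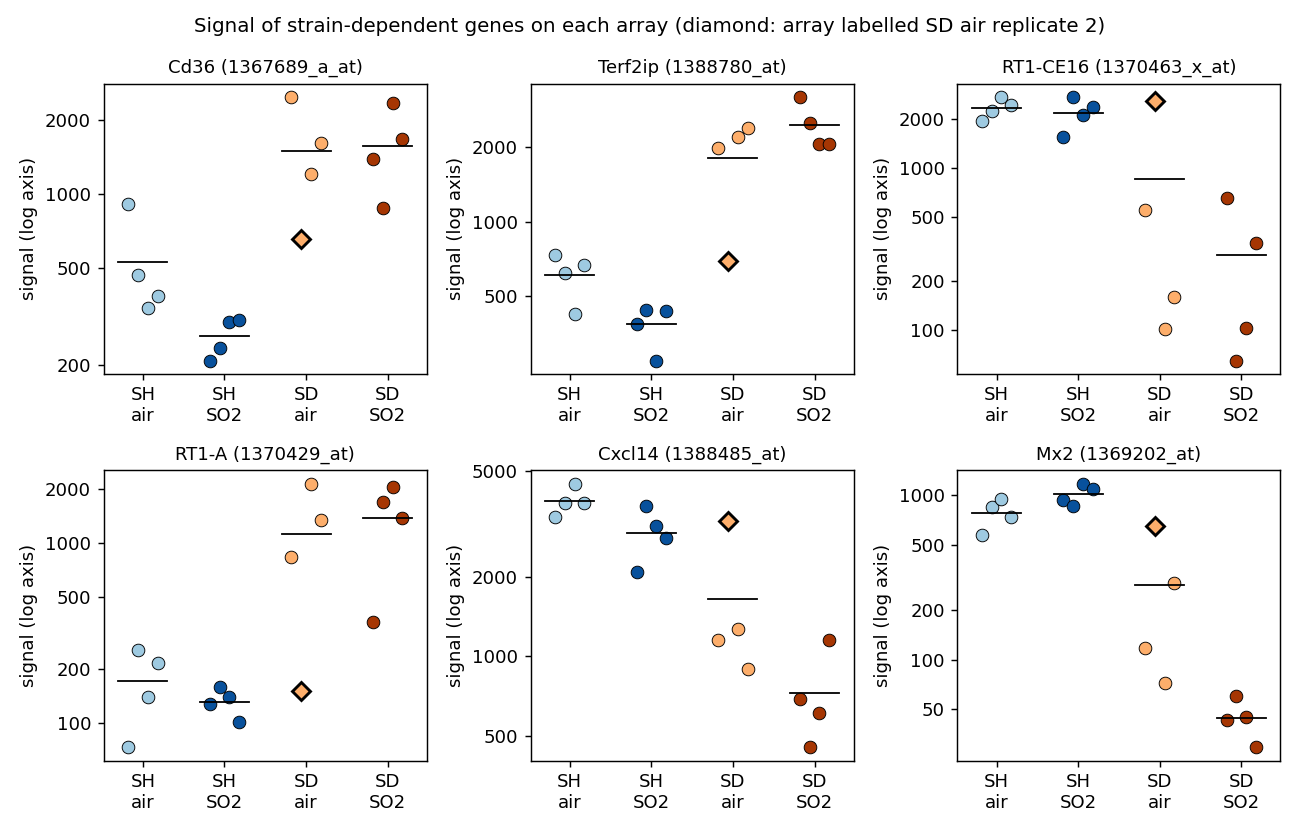
Signal on each array (log axis) of 6 probe sets that differ between the strains, in the 4 groups, with lines at the group means; these were picked after their values were seen. The diamond is the array labelled SD air replicate 2, with 693.8 for Terf2ip among SH air arrays at 424.8 to 733.2.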

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

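The tests of other splits of the arrays were set before their results were seen, except the unadjusted count for the strains in SO2, set after; the tests on strain markers, probe sequence, array quality and clock phase were chosen after the results were seen, except that of array quality on the clock list. Splits of the same arrays into groups of the same size show where chance is argued against. For the called count of the strain difference in SO2 it is: 1 of 35 splits, the real one, gave 90 called probe sets, and the highest other gave 1. That is the smallest share that 35 splits can give, and it was not adjusted for the number of split tests. For the other comparisons, with 0 called, the number of splits with as many is fixed at all of them and decides nothing: 35 of 35 for SO2 in SH rats (highest other 1), 35 of 35 for SO2 in SD rats (4), 100 of 100 for the interaction (2) and 35 of 35 for the strains in air (4). At an unadjusted p under 0.05 chance was not excluded, with as many from 9 of 35 splits for SO2 in SH rats (537, highest other 831), 5 of 35 for SO2 in SD rats (915 and 1591), 36 of 100 for the interaction (516 and 1595), 5 of 35 for the strains in air (709 and 810) and 8 of 35 for the strains in SO2 (1127 and 2102). In air, the split with 4 called probe sets put SH air replicate 1 with SD air replicates 1, 3 and 4. It placed the array labelled SD air replicate 2 among SH arrays, so it largely follows strain if that array is SH-like. The splits in air therefore cannot decide between chance and a strain difference. The counts of called lists did not exclude chance either: 22 of 35 splits gave as many in SH rats (3, highest other 8), 5 of 35 in SD rats (8 and 9), 20 of 100 for the interaction (6 and 10), 11 of 35 for the strains in air (5 and 7) and 14 of 35 for the strains in SO2 (3 and 9).

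The array labelled SD air replicate 2 stood apart from its group in genes that differ between the strains. Of 70 strain markers called on the SO2 arrays alone, 56 with a difference over 0.5 between the SH air and the other SD air arrays were placed on a scale from 0 (mean of the other SD air arrays) to 1 (mean of the SH air arrays); its median position was 0.862 (95% bootstrap interval 0.781 to 0.919), against 0.862 for the lowest SH air array and at most 0.0101 for the other SD air arrays, and over all 70 markers, on a scale set by the SO2 arrays, it was 0.681 (0.627 to 0.781) against 0.7 for the lowest SH air array and at most 0.129 for the other SD air arrays. Background or RNA quality is argued against, since 0 of 3 measures lay outside the range of the other 15 arrays. A wrong label of this array may account for it, while no SH air array was SD-like; a smaller share of SD RNA mixed into the sample cannot be told apart, because its linear position of 0.876 (0.783 to 0.92) spans the lowest SH air array at 0.83. Variation between SD rats, an outbred stock, stays open and was not tested.

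The strain differences in SO2 may reflect expression or sequence differences under the probes. Background and RNA quality are argued against as the whole cause, since 133 probe sets were called with both quality covariates against 90 without. Sequence variants under the probes cannot be told apart from expression: other probe sets of 17 called genes shifted in the direction of the call by a median of 0.378 (95% bootstrap interval 0.00339 to 0.68) against 0.974 for the called ones, with 13 of 17 in the same direction and 2 called. MHC class I genes are also highly alike and polymorphic, so their probe sets can measure more than 1 gene or miss an allele. Genetic difference between the strains, which the design names, stays open as the biological explanation.

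Clock genes shifted with SO2 in SD rats at the preset correlation of camera, and did not pass with an estimated one (adjusted p = 0.115 with an estimated correlation). The array labelled SD air replicate 2 is argued against as the cause, since without it the adjusted p was 1.81e-05 at the preset correlation, and so are background and RNA quality, since with both covariates the mean change was 0.38 (0.398 without them) and the adjusted p 0.00039. A difference in clock phase between the animals of the groups is a candidate explanation: the genes whose transcripts peak opposite to the Per genes had a median change of -0.444 and the 12 others 0.632, 0 of them below 0. In SH rats the medians were -0.238 and 0.156, with 4 of the 12 below 0. The opposite genes were Bmal1, Nfil3 and Clock, and all 3 were below 0 in SH rats too. Their median of -0.444 in SD rats is the value of Nfil3 (SE 0.455). This division was chosen after the values were seen, so it is not independent evidence for phase. The signs in SD rats held without each SD array in turn, with medians of -0.56 to -0.321 and 0.442 to 0.774. Whether phase differed through the time of sampling or through SO2 was not tested, as the labels give no time of day.

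The strains' responses to SO2 differed, by the interaction test of camera at the preset correlation, in 6 lists: extracellular matrix genes by 0.236, T cell and natural killer cell genes by -0.21, cardiac and skeletal muscle genes by 0.398, adipocyte genes by 0.233, circadian clock genes by -0.403 and sterol and fatty acid synthesis genes by -0.169. None was called with an estimated correlation, where adjusted p ran from 0.231 to 0.544. Without the array labelled SD air replicate 2, T cell (adjusted p = 0.118), adipocyte (0.078) and sterol genes (0.056) were not called by camera. As many list calls came from 20 of 100 splits. The clock and matrix calls in the interaction, in SD rats and between strains in air all use the same SD air arrays. Likewise, the muscle, T cell and sterol calls in the interaction, in SD rats and between strains in SO2 all use the same SD SO2 arrays. The calls of a list in these comparisons are therefore not independent of one another.

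Of 448 groups of 4 arrays tested, over the named genes and array measures, 27 had 1 array far from the other 3, where chance gives 22. Signals of such arrays in SH air were 200.9 for Meg3 in replicate 2, 1089 for Myl7, 249.9 for Idi1 and 932.9 for Usp18 in replicate 3, and 323.7 for Mlc1 in replicate 1. In SH SO2 they were 431.5 for Meg3, 901.9 for Tapbp and 1857 for Ifngr1 in replicate 2, 588.5 for Myl7 and 838.4 for Cyp2f4 in replicate 1, and 312 for Mlc1 and 344.1 for Lum in replicate 4. In SD air they were 68.3 for Stap2 and 320 for Gp2 in replicate 4, 226.1 for Lum in replicate 3, and 693.8 for Terf2ip and 282.7 for Gsta3 in the array labelled replicate 2. In SD SO2 they were 309.2 for Loxl1, 214.2 for Pck1 and 204.9 for Clock in replicate 1, 565.5 for Nsmaf, 2995 for Stat3 and 219.7 for Ifit3 in replicate 2, 110.9 for Stap2 in replicate 3, and 21200 for Defb4 and 1413 for Inmt in replicate 4. The actin 3' to 5' ratio was 2.94 on SD SO2 replicate 2.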

How the results depend on the processing

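The quality covariates, alone, together or without the array labelled SD air replicate 2, and the exclusion of the 2 arrays of highest actin ratio were chosen after seeing the data. No called gene or list changed sign in any setting, while some values that were not called did, such as Cd36 for SO2 in SD rats (0.15, lowest -0.19), Suox there (-0.16, highest 0.044), Ephx2 for SO2 in SH rats (-0.026, highest 0.09) and Myl7 for the interaction (0.75, lowest -0.043). The small values of Ephx2 and Suox, called nowhere, moved over 1.5 times without single arrays in most comparisons. Over the analysis choices fixed beforehand, 3710 values of named genes stayed on their side of the threshold, 140 calls were lost and 43 gained; for called lists 621 stayed and 128 were lost. Dim probe sets limit what can be seen, since the 10th percentile of signal was 17 to 26.8 on every array against an offset of 16. Unless the alternative's own construction shows it, the cause was not tested.

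For the strains in air (0 probe sets called) the count was 5 with an offset of 64, 1 with no filter, 1 without the trend, 28 with array weights, 1 with the actin ratio, 2 with both covariates and 92 with both covariates and without the array labelled SD air replicate 2; its lists (5) numbered 8 with quantile normalization and 3 with the title number. For the strains in SO2 (90) the count was 154 with both covariates and without that array. Its lists (3) numbered 9 with an offset of 64, 9 with median-centred arrays, 5 with no filter, 6 with the lower 50% left out, 10 with the groups' own arrays, 7 with the actin ratio and 6 without the 2 arrays of highest actin ratio. SH lists with SO2 (3) numbered 1 with the 10th percentile, 0 with both covariates and 0 with both and without that array, where SD lists (8) numbered 5. With an estimated correlation 0 lists were called in each comparison, and with fry in a direction 0 in SH rats, 1 in SD rats, 0 for the interaction, 0 in air and 0 in SO2; without regard to direction fry called 1, 1, 0, 3 and 12.

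Leaving out each array in turn gave called probe sets of 0 to 1 for SO2 in SH rats, 0 to 3 for SO2 in SD rats, 0 to 0 for the interaction, 0 to 86 for the strains in air and 50 to 115 for the strains in SO2; called lists ranged over 3 to 5, 5 to 10, 3 to 8, 2 to 7 and 2 to 9. The 5 in SH rats was without SH air replicate 3.

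Replicate numbers were given here in title order, and the labels name no pairing of arrays between groups. Deviations of 24 same-numbered pairs correlated from -0.433 to 0.151, 4 over 0.1, and 1 of 16 arrays correlated best with its own number. These values therefore cannot show whether animals were paired in the design. With the replicate block the counts were 0, 0, 0, 0 and 86 in the order above, the lists for the strains in SO2 numbered 8, and the block ended the calls of the adipocyte list in the interaction and of some named genes in SO2, such as Tesc and Mx2.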

Other observations

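Contrasts averaged over both strains or both exposures were chosen after the results were seen, with the splits of their called counts set before and those of their unadjusted counts after. Averaged over the strains, SO2 had its smallest adjusted p at Srsf5, a splicing factor (0.63, SE 0.104, adjusted p = 0.075), then at Slfn4, of a family induced by interferon (0.70, SE 0.14), and Dnajb1, a heat shock co-chaperone (-0.59, SE 0.12), both at an adjusted p of 0.166. Limma called 0 probe sets, with 939 at an unadjusted p under 0.05, and 100 of 100 splits gave as many (highest other 2), which a count of 0 fixes and which decides nothing; at an unadjusted p 7 of 100 gave as many (highest other 1300), and chance was not excluded. Averaged over the exposures, 170 probe sets differed between the strains, led by Cd300c2 (-1.14, adjusted p = 1.71e-05), Terf2ip (-2.02, adjusted p = 1.75e-05) and Defb4 (-1.04, adjusted p = 1.97e-05). There chance is argued against: 1 of 100 splits, the real one, gave as many, and the highest other gave 1. That is the smallest share that 100 splits can give. At an unadjusted p 3 of 100 gave as many (1292, highest other 1309).

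Across the 11106 probe sets, which are not independent replicates, the SO2 effects of the strains correlated with r = 0.105 (rho = 0.134), and the strain differences in air and in SO2 with r = 0.345 (rho = 0.199).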
